A study of Mus musculus with 8 samples.

How the data were processed

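Dendritic cells grown from the bone marrow of C57BL/6 mice, a standard inbred laboratory strain, were cultured with GM-CSF at 40 ng/ml, a growth factor that drives marrow cells towards dendritic cells, and the non-adherent cells were taken on day 9, per the labels' protocols. The cells were then left overnight with or without the class B CpG oligonucleotide ODN1826 at 10 µM. CpG oligonucleotides are short DNAs with unmethylated CG pairs that are sensed by Toll-like receptor TLR9. The control is described as medium alone in 1 part of the labels and as PBS in another. Total RNA was labelled with Cy3 and hybridised to mouse miRNA arrays in 1 colour, with 4 untreated and 4 CpG-treated samples on the 8 arrays of 1 slide. The labels name the replicates by number and do not say that they came from separate animals or cultures, so p-values measure the spread between these samples, which may be technical in part.

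The authors deposited the scanner output of each array, made with Agilent Feature Extraction 9.5.3.1 per the file headers, in which the processed signal is an intensity per spot after background subtraction and spatial detrending, with no scaling between arrays. Each array's deposited summary gives a total gene signal, also an intensity, and a detection flag per miRNA. The authors' series table holds intensities of 260 miRNAs. All 2080 of its values equalled the deposited total gene signal within 0.1%, with 41 values at 0.01, the value given to signals at or below 0. It had been planned as an alternative in the belief that the authors had normalized it, and it is used here as an unscaled table. limma is named without a version in the submitters' processing notes, and how the authors applied it is not given in the sources used here.

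From the spots, the mean processed signal over spots without outlier flags was taken for each probe, and then the mean over the probes of each miRNA, for 567 mouse miRNAs and 10 miRNAs of a mouse gammaherpesvirus. Signals were divided by each array's 75th percentile over the 177 mouse miRNAs detected on all 8 arrays. Values below a floor of 0.0107 (log2 of -6.55), the median over arrays of the lowest scaled signal among detected miRNAs, were set to it before log2 was taken. A value of 0 on this log2 scale is thus the array's 75th percentile. A miRNA was tested if it was detected on at least 3 of the 4 arrays of a group, which left 212. Probes of a miRNA well above background on all arrays had the same sign of change in 129 of 134 miRNAs with more than 1 such probe, among them all 17 called ones of that kind.

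The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 212 miRNAs and a threshold of 0.05. Of the 14 miRNA lists, 11 had at least 3 tested members and were tested with camera at a preset correlation of 0.01. Camera with an estimated correlation and fry, which tests whether a list's members move on balance one way without setting them against other miRNAs, were run beside it. Adjustment was over the 11 lists. Array-level measures were compared by exact two-sided permutation of the 70 arrangements of 4 and 4 arrays, where the smallest possible p is 0.0286. A miRNA detected on all 4 arrays of one group and none of the other has only a bound for its fold. The bound sets the mean of the detected group against, per array of the other, the higher of the miRNA's own value and the lowest signal well above background. The number of arrays limits the precision of every value.

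The design, the lists, the alternatives and the rule for named miRNAs were fixed before the data were examined. The rule took the 12 largest increases and the 12 largest decreases among miRNAs past the threshold whose groups did not overlap, every detected member of the TLR-responsive and miR-99b lists, up to 4 members of highest mean signal from each other list, and up to 5 miRNAs detected in one group only in each direction. The alternatives were other scalings, backgrounds, probe summaries, filters, floors and limma options, the replicate number or the slide row as a block, and leaving out each array. Those chosen after seeing the data were median-of-ratios scaling, cyclic loess, scaling on 4 bright control features named hur on the array, and leaving out the CpG arrays of replicates 2 and 4. Python 3.11.15 and matplotlib 3.10.9 drew the figures.

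The fit was tested on simulated data for the comparison of CpG with untreated, in 50 runs over the 212 miRNAs with 40 changed. It recovered 89.7% of miRNAs changed by 1 and 99.8% of those changed by 2 on the log2 scale, and 3.76% of calls were false. Camera recovered 100% of lists of 10 members shifted by 0.5 and called 4% of unshifted lists at an unadjusted p under 0.05. These simulated values were independent between miRNAs, which the real ones are not. Coordinates are those of the array's annotation (mm9), which give the span of the probe's target on the miRNA. Host gene names come from the NCBI gene table for GRCm38, used for names only. Probe sequences were not used here, so that GC content was not checked.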

Results

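miRNA levels were measured in 8 samples of mouse bone-marrow-derived dendritic cells, 4 left untreated and 4 exposed overnight to the CpG oligonucleotide. The comparison asks which miRNAs differ between untreated cells and cells exposed to this TLR9 ligand. No sample had a control oligonucleotide, so that signalling through TLR9 cannot be told apart from other effects of the oligonucleotide. Before scaling, the 75th percentile of miRNA signal was between 101 and 144 intensity units on the untreated arrays and between 157 and 280.5 on the CpG arrays. Scaled log2 values correlated across miRNAs with r between 0.975 and 0.994 within the untreated group, between 0.968 and 0.995 within the CpG group and between 0.947 and 0.985 across groups. Those correlations are across miRNAs, which are not independent replicates.

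miR-155, a miRNA induced by Toll-like receptor signalling, rose 3.79-fold with CpG. Its log2 signal went from 2.30 ± 0.48 to 4.22 ± 0.20 (SD, n = 4 each), a difference of 1.92 (SE 0.24, limma adjusted p = 0.00096). miR-877, which lies within Abcf1, rose 4.07-fold, from -3.52 ± 0.14 to -1.50 ± 0.42 (SD, n = 4 each), with a log2 difference of 2.02 (SE 0.21, limma adjusted p = 0.00062). miR-222 rose 2.21-fold (log2 1.14, SE 0.20, limma adjusted p = 0.0111). The array annotation places the target of miR-155 on chromosome 16 at 84714393 to 84714410, within Mir155hg, that of miR-877 on chromosome 17 at 36097740 to 36097752, and that of miR-222 on chromosome X at 18724029 to 18724042.

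In the list of TLR-responsive miRNAs, 11 of 12 members could be tested, and 4 rose and 0 fell, with 4 past the threshold adjusted over the list alone. Beside miR-155 and miR-222 these were miR-147, on chromosome 2 at 122466590 to 122466607, which rose 1.96-fold (log2 0.97, SE 0.21, limma adjusted p = 0.0227), and miR-146a, a feedback regulator of Toll-like receptor signalling on chromosome 11 at 43187937 to 43187955, which rose 1.89-fold (log2 0.92, SE 0.24, limma adjusted p = 0.0355). The other 7 members did not pass. Their log2 differences were 0.42 for miR-221, -0.07 for miR-146b, -0.31 for miR-132, -0.23 for miR-212, -0.11 for miR-21, -0.04 for miR-9 and -0.15 for miR-9*. miR-187 was not detected on any array. The list lay 0.45 above the other miRNAs on the log2 scale (camera adjusted p = 0.046), with a mean of 0.41 and a median of -0.04 that differ in sign. Against no change rather than other miRNAs, fry gave an adjusted p of 0.13. Without scaling, where most miRNAs shift upward, the mean was 1.20 and the list passed (fry adjusted p = 0.0092). The camera call was lost with an estimated correlation (adjusted p = 0.80) and without any 1 of untreated replicates 2, 3 and 4 and CpG replicate 1, as was that of miR-147 without untreated replicate 2 or CpG replicate 3 (limma adjusted p = 0.0731 and 0.0669) and that of miR-146a in 6 of the 8 fits that leave out 1 array (limma adjusted p up to 0.102). When the arrays were not scaled, miR-221, miR-146b and miR-21 rose past the threshold, by 1.22, 0.73 and 0.69, and miR-212, at 0.57 there, passed in the authors' deposited table and on the control features.

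**Figure D1:**
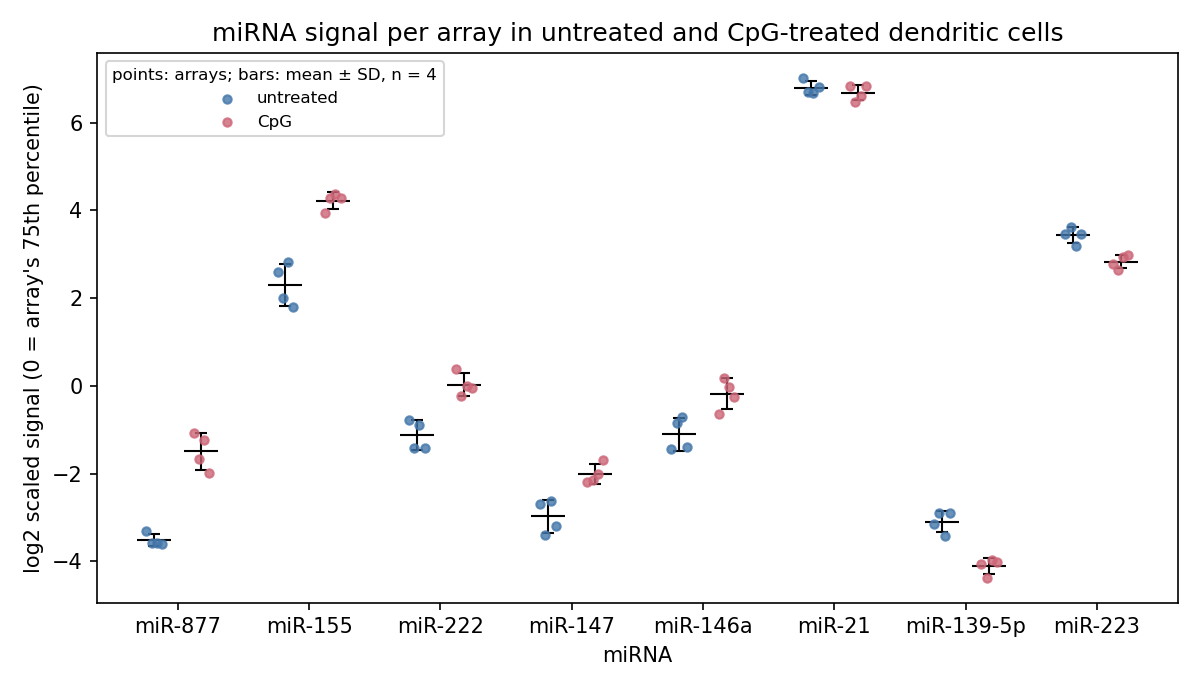
Log2 scaled signal of 8 named miRNAs on each array (points), with the mean and SD of 4 arrays per group, on an axis where 0 is the array's 75th percentile. The CpG arrays lie above the untreated ones for miR-877, miR-155, miR-222, miR-147 and miR-146a and below them for miR-139-5p and miR-223, which turns to 0.20 above without scaling, while the groups overlap for miR-21.

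Across the 212 miRNAs tested, 30 passed the threshold, 16 higher and 14 lower with CpG, and 85 had an unadjusted p under 0.05. The groups did not overlap for 57 miRNAs (26.9%), against 2.86% expected for each miRNA by chance. miRNAs vary together across the arrays, so that this share does not exclude chance. Of the 16 that were higher, 6 changed by more than 2-fold, as did 5 of the 14 that were lower. Among the higher ones with the largest changes were also miR-292-5p (log2 1.22, and 0.55 with a floor 2 times higher), detected on 1 of 4 untreated arrays and near the floor on others, miR-674 (1.21), miR-101b (0.75) and 4 passenger arms, miR-135a* (0.86), miR-29b* (0.84), miR-21* (0.76) and miR-22* (0.74). miR-674 read -6.53 on untreated replicate 4, near the floor of -6.55. It was at 0.87 to 1.44 when 1 array was left out and passed in 16 of 28 alternatives. The median log2 difference of the tested miRNAs was -0.19. Relative to it, miR-155 was higher by 2.11 and miR-877 by 2.22.

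The largest decreases among miRNAs measured in both groups without overlap were in miR-138 (log2 -1.40, SE 0.34, limma adjusted p = 0.0284), miR-191* (-1.23, SE 0.14), miR-801 (-1.04, SE 0.25), miR-139-5p (-1.01, SE 0.17, limma adjusted p = 0.00768) and miR-30c (-0.81, SE 0.15, limma adjusted p = 0.0127). miR-139-5p lies within Pde2a, at 108623901 to 108623917 on chromosome 7. miR-191* was detected on 2 of 4 CpG arrays and sat near the floor there, so that its fold depends on the floor, and with a floor 2 times higher it was -0.24 (limma adjusted p = 0.14). Without scaling none of the 5 passed, at -0.60, -0.56, -0.24, -0.21 and -0.011 in the order named (limma adjusted p = 0.24, 0.083, 0.35, 0.43 and 0.97), and miR-138 passed in 14 of 27 alternatives. A further 7 lower miRNAs were miR-712 (-0.72), miR-484 (-0.66), miR-192 (-0.62), miR-223 (-0.60), miR-26a (-0.60), miR-16 (-0.49) and let-7d (-0.45), and all 7 turned positive, between 0.083 and 0.35, without scaling. Relative to the median, miR-223, a myeloid miRNA on chromosome X at 93438224 to 93438244, lay at -0.41 and let-7d at -0.26.

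The number of miRNAs called lower differed between scalings. The share of calls that were higher was 53.3% as reported, 100% without scaling (88 higher, 0 lower), 100% in the authors' deposited table (87 higher, 0 lower), 97.2% on the control features (70 and 2), 77.3% with median-of-ratios scaling (17 and 5), 69.6% with the 75th percentile over all miRNAs (16 and 7), 64.7% with cyclic loess (11 and 6), 61.1% with the median (11 and 7), 58.3% with normexp and quantile (7 and 5), and 47.4% with quantile normalization (9 and 10). Leaving out 1 array also moved the counts of higher and lower calls, to 8 and 4 without untreated replicate 1, 3 and 2 without untreated replicate 2, 10 and 7 without untreated replicate 4, 39 and 29 without CpG replicate 1, 8 and 3 without CpG replicate 2, and 3 and 2 without CpG replicate 3. Without untreated replicate 2, and likewise without CpG replicate 3, the calls kept were miR-877, miR-155, miR-222, miR-139-5p and miR-191*. With the 2 brightest CpG arrays left out, 3 were higher and 1 lower.

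**Figure D2:**
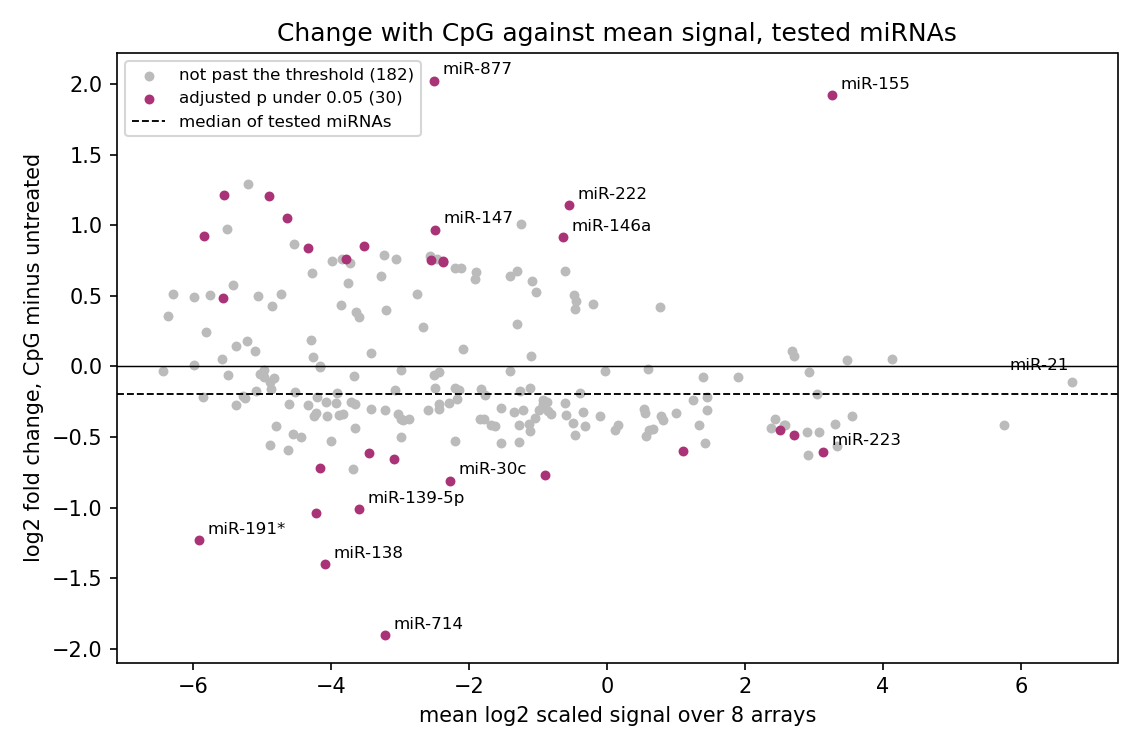
Log2 difference between CpG and untreated arrays against mean log2 scaled signal for the 212 tested miRNAs, with the 30 past the limma threshold coloured and the median of -0.19 dashed. miR-155 and miR-877 lie highest and miR-714 (-1.90), named here after its values were seen and with groups that overlap, lies lowest. miR-223 lies below 0 here and at 0.20 without scaling.

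The miR-17 and let-7 families lay below the other miRNAs after scaling, as did other lists that did not pass. None of the 12 tested members of the list named miR-17 family, which is linked to proliferation, passed the threshold. Beside miR-17 that list holds, among others, miR-18a, miR-19a, miR-19b, miR-25, miR-92a and the passenger arm miR-17*. The list lay at -0.33 against the others (camera adjusted p = 0.046). Of the 9 let-7 members, let-7d passed and 6 did adjusted over the list alone, and the list lay at -0.36 against the others (camera adjusted p = 0.04998). Tested with fry against no change, the miR-17 members had a mean of -0.34 and the let-7 members of -0.37 (fry adjusted p = 0.038 and 0.043), and without scaling these means turned to 0.46 and 0.43 (fry adjusted p = 0.12 and 0.18). With an estimated correlation neither list passed (adjusted p = 0.80 for both), nor did they without scaling, at -0.32 and -0.34 against the others (camera adjusted p = 0.51 and 0.37). Of these 2 lists, miR-92a differed by -0.49 and let-7a by -0.47 without passing (limma adjusted p = 0.0566 for both), and without scaling they were at 0.31 and 0.33.

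The other lists did not pass the camera test as reported. With no filter on dim miRNAs, the miR-15/16, miR-23/27/24, miR-29/30 and granulocyte and myeloid lists passed it. The miR-15/16 family also did without the 2 brightest CpG arrays. Against no change and without scaling, fry called the miR-148, miR-23/27/24, miR-29/30 and granulocyte and myeloid lists. Their means there were 0.56, 0.46, 0.46 and 0.52 (fry adjusted p = 0.025, 0.046, 0.047 and 0.047). miR-16, which is also the single tested member of the erythroid list, was the 1 of 7 tested members of the miR-15/16 family past the threshold, and miR-30c the 1 of 8 in the miR-29/30 families. These lists lay at -0.33 and -0.32 against the others, much like the miR-17 family at -0.33, and the camera adjusted p was 0.26 for both. In the granulocyte and myeloid list miR-223 was the 1 of 6 past it (list at -0.26, adjusted p = 0.26). None of the 7 members of the miR-23/27/24 clusters passed (list at -0.32, adjusted p = 0.26), nor any of the 4 of the miR-99b cluster (adjusted p = 0.97), the 3 of the miR-148 family (adjusted p = 0.61), the 3 tested lymphoid and progenitor markers (adjusted p = 0.47), among them miR-10a at -0.54, or the 4 tested miRNAs of non-marrow tissues (adjusted p = 0.97). In the stromal list only miR-10b was detected on any array, and it was not tested. Among the viral probes, mghv-miR-M1-2 was detected on all 8 arrays, at -2.84 ± 0.41 in untreated and -2.51 ± 0.50 in CpG samples (SD, n = 4 each, exact permutation p = 0.40), and 3 others were detected on 2 arrays each.

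There were 4 miRNAs detected on all 4 CpG arrays and on 0 untreated arrays. miR-96 was 2.07-fold higher (limma adjusted p = 0.0375), miR-874 1.89-fold (limma adjusted p = 0.0227) and miR-467e 1.40-fold (limma adjusted p = 0.0474). miR-715 was 1.18-fold higher and did not pass (limma adjusted p = 0.57). All 4 bounds equalled the fitted folds, so that they are not firm lower limits. Without untreated replicate 4, miR-96 was at log2 0.82, against 1.05 with all arrays. With a floor 2 times higher, miR-874 was at log2 0.24 and miR-467e at 0.22 and neither passed (limma adjusted p = 0.23 and 0.11), so that their bounds and calls depend on the floor. Leaving out 1 array also ended the call of miR-96 (without untreated replicate 2 or 4 or CpG replicate 2 or 3), miR-874 (untreated replicate 1 or 2 or CpG replicate 3) and miR-467e (untreated replicate 1, 2 or 4 or CpG replicate 2, 3 or 4), and across all alternatives they passed in 20 of 27, 19 of 27 and 10 of 27. None was found in the opposite direction. The detection flag comes from each array's deposited output, which is not scaled between arrays. The CpG arrays were 1.74-fold brighter at the 75th percentile, so that brightness alone could give detection in that group only. Whether it did was not tested.

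More miRNAs were detected with CpG, 223 ± 11.6 against 195 ± 5.56 in untreated samples (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible). Counted by spots well above background, the difference was 21.5 (exact permutation p = 0.40). The 75th percentile before scaling was 217 ± 58.5 with CpG and 122 ± 17.5 without (SD, n = 4 each, exact permutation p = 0.0286), a 1.74-fold difference of geometric means. Of the control features, hur_1 was 1.15 times as bright on the CpG arrays (exact permutation p = 0.0286), and hur_2, hur_4 and hur_6 were 1.20, 1.23 and 1.15 times as bright (exact permutation p = 0.057, 0.14 and 0.34), as ratios of geometric means.

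**Figure D3:**
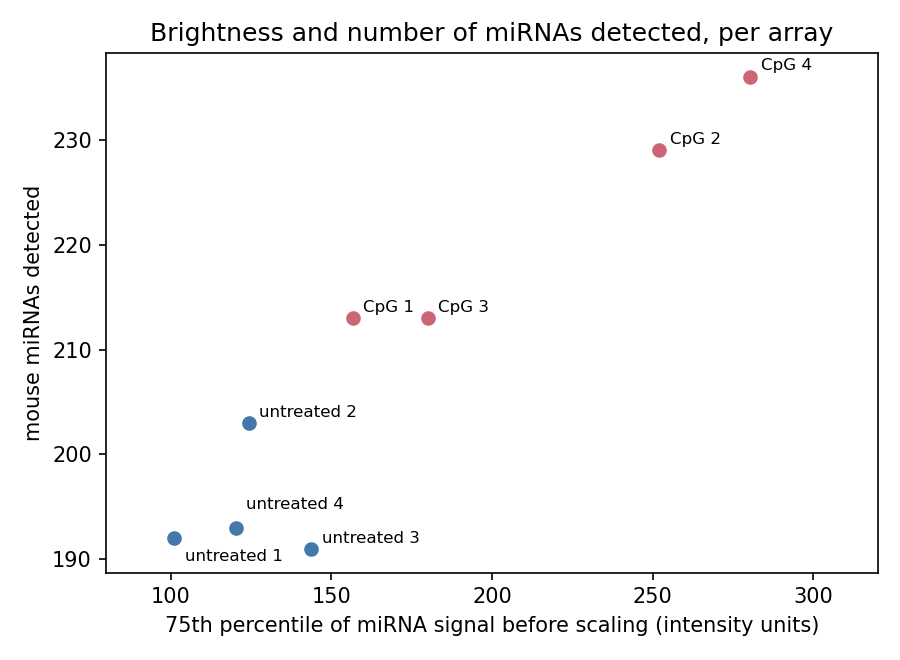
Number of mouse miRNAs detected against the 75th percentile of miRNA signal before scaling, in intensity units, with 1 point per array. The 4 CpG arrays lie above and to the right of the 4 untreated arrays, and CpG replicates 2 and 4 are the brightest, at 252 and 280.5.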

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

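All tests of explanations in this part were chosen after the result they bear on had been seen. The CpG arrays were brighter before scaling, by 0.80 on the log2 scale at the 75th percentile of the miRNAs. A gain of labelling, hybridisation or scanning acting on unchanged RNA would raise the hur control features as much, but these rose by 0.24, leaving a difference of 0.56 in which the 4 CpG arrays lay above the 4 untreated ones (exact permutation p = 0.0286), which argues against such a gain as the whole cause. This holds if the RNA that hur features measure did not change, which the sources used here do not state. Background left in the processed signal would raise the negative control spots. Their mean was lower by 0.47 units in the CpG group (difference -0.47, exact permutation p = 0.31), while the 75th percentile of the miRNAs went from 122 to 217 units. These spots were read after background subtraction, so that the test cannot show whether background differed before it. More miRNA per amount of RNA in the CpG cells cannot be told apart from what is left, since 0 of the 6 control features named dmr had a mean signal over 10 units and no spike of known amount was used here.

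The count of 30 called miRNAs was set against other groupings of the arrays. Of the 35 splits of the 8 arrays into 4 and 4, 2 gave as many calls, the real one with 30 and another with 40, so that chance could not be excluded for the count. The other split exchanges untreated replicate 3 and CpG replicate 1. It shares 1 called miRNA with the real split, and the remaining 33 splits gave 0 calls, among them the split by slide row. With slide row as a block 13 miRNAs were higher and 15 lower. The sides of the split with 40 calls did not overlap in hur_4, at 7683 to 8571 against 9048 to 13768. Nor did they in hur_6, at 21520 to 29246 against 30115 to 44845. In hur_1, hur_2 and the 75th percentile of the miRNAs they overlapped. These features were compared after the counts had been seen, and no cause of that split was tested.

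Among 157 groups of 4 arrays checked, 8 held 1 array far from the other 3, where chance gives about 1 in 20. The array's log2 signal, and the mean of the other 3 in its group, were -3.32 and -3.59 for miR-877 and -3.13 and -3.90 for miR-801, both on untreated replicate 1. On CpG replicate 2 they were 0.47 and 0.90 for miR-26a and 0.94 and 1.42 for miR-23b. They were 0.63 and 0.30 for miR-106b on CpG replicate 4, and -6.19 and -4.63 for miR-206 on CpG replicate 1. Untreated replicate 2 had 203 mouse miRNAs detected against a mean of 192 on the others. The control feature hur_1 read 59043 on CpG replicate 4 against a mean of 44807, and in the CpG group as a whole it was 1.16 times as bright as in the untreated group by arithmetic means, a difference between groups in a control feature.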

How the results depend on the processing

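The alternatives of median-of-ratios scaling, cyclic loess, scaling on the control features and leaving out CpG replicates 2 and 4 were chosen after seeing the data. Across 28 alternatives miR-877 (log2 difference 0.73 to 2.82) and miR-155 (1.70 to 2.72) passed the threshold in all 28, miR-222 in 26, miR-147 in 24 and miR-139-5p in 23. Among all values of named miRNAs under alternatives, 1430 kept their direction and side of the threshold (counting miR-21 at 0 with quantile normalization), 255 were no longer past it, 68 newly passed and 198 changed sign, most of them in neither setting past it. The 255 include a value of miR-467e* taken for miR-467e where only miRNAs detected on all 8 arrays were tested. Signal over background limits the dim miRNAs. Except where the construction shows it, the cause was not tested.

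The counts of higher and lower calls, 16 and 14 as reported, were 9 and 10 with quantile normalization, 88 and 0 without scaling, 87 and 0 in the authors' deposited table, 7 and 5 with normexp and quantile, 2 and 1 with no filter, where 567 miRNAs were tested, 57 and 65 with array weights, 70 and 2 on the control features, and 3 and 1 without the 2 brightest CpG arrays. Lower calls were 7 with the 75th percentile over all miRNAs, 7 with the median, 4 with the brightest probe, 34 with a floor 2 times higher, 28 with trend and robust, 5 with median-of-ratios scaling and 6 with cyclic loess. Leaving out each array gave 3 to 39 higher and 2 to 29 lower calls. Without scaling 122 miRNAs had an unadjusted p under 0.05, and 121 in the authors' deposited table. The median log2 difference was 0.60 without scaling, 0.36 on the control features and 0.051 with median of ratios. The difference in detected miRNAs was 21.5 by spots well above background.

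With the replicate block, 16 miRNAs were higher and 22 lower. It kept 27 of the 30 calls, and let-7d, miR-135a* and miR-21* were no longer called. Deviations of same-numbered samples correlated at 0.28, -0.26, 0.25 and 0.096, which neither shows that the numbers pair the samples nor excludes it, and not every sample correlated best with its own number. The labels do not say that same-numbered samples share an animal. Their descriptions do give both the same name and number, with CpG added for the treated sample, and their arrays lie side by side on the slide. A pairing thus stays possible. With that block the lists lay at 0.45 (TLR-responsive), -0.33 (miR-17) and -0.36 (let-7), all at adjusted p = 0.0775.

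The TLR-responsive list passed in 15 of 30 alternatives, the miR-17 family in 14 and the let-7 family in 10 (adjusted p from 0.0062, 1.1e-06 and 2.8e-06 up to 0.80, 0.83 and 0.80), with no change of sign in these 3. The alternatives include fry, which tests a list against no change and which the TLR-responsive list, with a mean of 0.41, did not pass (adjusted p = 0.13). Fry without scaling, which is not among the alternatives counted, gave that list a mean of 1.20 (fry adjusted p = 0.0092). The 3 lists no longer passed camera at shifts, in that order, of 0.43, -0.26 and -0.15 with quantile normalization, 0.47, -0.32 and -0.34 without scaling, 0.43, -0.35 and -0.38 in the authors' deposited table, 0.47, -0.32 and -0.35 on the control features, 0.45, -0.33 and -0.36 with the 75th percentile over all miRNAs, 0.45, -0.33 and -0.36 with the median, 0.46, -0.33 and -0.36 with median of ratios, and 0.45, -0.33 and -0.36 with an estimated correlation. The miR-17 and let-7 families were also lost at -0.11 and -0.10 with normexp and quantile, -0.26 and -0.16 with cyclic loess, and -0.28 and -0.31 when only miRNAs detected on all 8 arrays were tested. The TLR-responsive list was lost at 0.48 and let-7 at -0.38 with array weights, and let-7 at -0.36 with the total gene signal and with slide row as a block. Leaving out each array gave 0.36 to 0.53, -0.39 to -0.27 and -0.42 to -0.29, and all 3 were lost without untreated replicates 2, 3 or 4 or CpG replicate 1, and let-7 also without untreated replicate 1.

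Of 198 changes of sign among named miRNAs, 124 were without scaling, in the authors' deposited table or on the control features, where most miRNAs shift upward. In 43 of the 198 the miRNA passed the threshold in one of the 2 settings. Without scaling and in the authors' deposited table, in that order, they were 0.083 and 0.081 for miR-712, 0.14 and 0.14 for miR-484, 0.18 and 0.18 for miR-192, 0.20 and 0.19 for miR-223, 0.20 and 0.20 for miR-26a, 0.31 and 0.31 for miR-16, 0.35 and 0.35 for let-7d, 0.73 and 0.72 for miR-146b, 0.49 and 0.49 for miR-132, 0.57 and 0.57 for miR-212 and 0.69 and 0.69 for miR-21. For others they were, in that order, 0.76 and 0.76 for miR-9, 0.65 and 0.65 for miR-9*, 0.43 and 0.42 for miR-99b, 0.39 and 0.39 for let-7e, 0.49 and 0.49 for miR-125a-5p, 0.58 and 0.58 for miR-19b, 0.42 and 0.42 for miR-20a, 0.31 and 0.31 for miR-92a, 0.50 and 0.49 for miR-106b, 0.39 and 0.39 for let-7f and 0.33 and 0.33 for let-7a. Further ones were 0.76 and 0.76 for let-7i, 0.50 and 0.49 for miR-148b, 0.74 and 0.74 for miR-148a, 0.46 and 0.46 for miR-152, 0.45 and 0.45 for miR-24, 0.24 and 0.23 for miR-23a, 0.17 and 0.17 for miR-27a, 0.49 and 0.49 for miR-23b, 0.34 and 0.33 for miR-15b, 0.38 and 0.38 for miR-15a and 0.43 and 0.43 for miR-322. The remaining ones were 0.56 and 0.56 for miR-29c, 0.31 and 0.31 for miR-30d, 0.60 and 0.60 for miR-142-3p, 0.38 and 0.38 for miR-342-3p, 0.73 and 0.72 for miR-34a, 0.61 and 0.61 for miR-181a, 0.56 and 0.56 for miR-181b, 0.26 and 0.25 for miR-10a, 0.21 and 0.20 for miR-200b, 0.62 and 0.62 for miR-200c and 0.74 and 0.73 for miR-141. On the control features they were 0.071 for miR-16, 0.11 for let-7d, 0.49 for miR-146b, 0.25 for miR-132, 0.33 for miR-212, 0.45 for miR-21, 0.52 for miR-9, 0.41 for miR-9*, 0.19 for miR-99b, 0.15 for let-7e, 0.25 for miR-125a-5p and 0.34 for miR-19b. They were also 0.18 for miR-20a, 0.067 for miR-92a, 0.26 for miR-106b, 0.15 for let-7f, 0.093 for let-7a, 0.52 for let-7i, 0.26 for miR-148b, 0.50 for miR-148a, 0.22 for miR-152, 0.21 for miR-24, 0.25 for miR-23b and 0.096 for miR-15b. The rest were 0.14 for miR-15a, 0.19 for miR-322, 0.32 for miR-29c, 0.074 for miR-30d, 0.36 for miR-142-3p, 0.14 for miR-342-3p, 0.49 for miR-34a, 0.37 for miR-181a, 0.32 for miR-181b, 0.016 for miR-10a, 0.38 for miR-200c and 0.50 for miR-141. With median of ratios they were 0.17 for miR-146b, 0.016 for miR-212, 0.13 for miR-21, 0.21 for miR-9, 0.092 for miR-9*, 0.030 for miR-19b, 0.21 for let-7i, 0.18 for miR-148a, 0.0037 for miR-29c, 0.049 for miR-142-3p, 0.17 for miR-34a, 0.055 for miR-181a, 0.0078 for miR-181b, 0.070 for miR-200c and 0.18 for miR-141. The brightest probe gave -0.10 for the non-marrow tissue miRNAs list, 0.075 for miR-146b, 0.015 for miR-21, 0.10 for miR-9, 0.017 for miR-9*, 0.088 for let-7i, 0.10 for miR-148a, 0.070 for miR-34a, 0.024 for miR-200c and 0.060 for miR-141. Normexp and quantile gave -0.00046 for the non-marrow tissue miRNAs list, 0.16 for miR-146b, 0.024 for miR-19b, 0.20 for let-7i, 0.12 for miR-29c, 0.072 for miR-142-3p, 0.12 for miR-34a, 0.0015 for miR-141 and -0.0017 for miR-715. Cyclic loess gave -0.055 for the non-marrow tissue miRNAs list, 0.21 for miR-146b, 0.19 for miR-21, 0.066 for miR-19b, 0.27 for let-7i, 0.030 for miR-29c, 0.12 for miR-142-3p and 0.22 for miR-34a. Quantile normalization gave 0 for miR-21, no change of sign, and 0.18 for miR-146b, 0.027 for miR-19b, 0.21 for let-7i, 0.14 for miR-29c, 0.076 for miR-142-3p and 0.14 for miR-34a. Without the 2 brightest CpG arrays they were -0.017 for the non-marrow tissue miRNAs list, 0.050 for miR-146b, 0.45 for miR-9, 0.18 for miR-9*, 0.13 for miR-148a, 0.17 for miR-34a and 0.075 for miR-181a. Array weights gave 0.030 for miR-146b, 0.24 for miR-9, 0.025 for miR-9* and 0.12 for miR-148a. The 75th percentile over all miRNAs gave 0.020 for miR-9 and 0.022 for let-7i. Testing with no filter gave -0.060 for the non-marrow tissue miRNAs list. A floor 2 times higher gave -0.0067 for the non-marrow tissue miRNAs list. Leaving out each array gave -0.20 to 0.059 for the miR-99b cluster, -0.026 to 0.13 for the non-marrow tissue miRNAs list, -0.13 to 0.0087 for miR-146b, -0.30 to 0.16 for miR-9, -0.36 to 0.052 for miR-9*, -0.088 to 0.0027 for let-7i, -0.14 to 0.013 for miR-148a, -0.068 to 0.16 for miR-29a, -0.088 to 0.21 for miR-29b, -0.24 to 0.081 for miR-34a and -0.15 to 0.042 for miR-141.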

Other observations

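The tests of the ratios between miRNAs in this part, cyclic loess, and the margin of 1 SE used with the matched lists were chosen after the results they bear on had been seen. The 2 arms of a hairpin come from 1 precursor, and their ratio on an array is free of scaling between arrays. Both arms were tested for 21 hairpins, and the ratio of passenger (star) to guide arm changed past the threshold in 5 of them, with 3 ratios higher and 2 lower. The ratio rose by 0.87 for miR-21 (SE 0.18, limma adjusted p = 0.00769), by 0.69 for miR-22 (SE 0.14, limma adjusted p = 0.00769) and by 0.77 for miR-29b (SE 0.18, limma adjusted p = 0.0117). It changed by -1.08 for miR-674 (SE 0.21, limma adjusted p = 0.00769) and by -0.67 for miR-7a (SE 0.20, limma adjusted p = 0.0459). The guide arm miR-674 read -6.53 on untreated replicate 4, near the floor of -6.55, and its ratio was not tested without that array. A ratio shows unequal change, not which arm changed. The trend with brightness described below does not cancel where the arms differ in signal, and the ratios were not corrected for it. For miR-21 the exact permutation test gave p = 0.0286 for 0.87, the smallest possible, as it also did for other hairpins. miR-222 and miR-221, which lie near each other on chromosome X, had a log2 ratio of -1.67 ± 0.42 in untreated and -0.95 ± 0.20 in CpG samples (SD, n = 4 each, exact permutation p = 0.057). That change of 0.72 did not pass 0.05 in this test, which does not pair the samples, and it stays open.

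The 21 star arms had a mean log2 difference of 0.21 after scaling. Random lists had a median of -0.017 at the signal of the star arms and -0.22 at that of the let-7 family, and this trend with brightness may account for the star arms. Their mean stood at the 95.92th percentile of 10000 random lists of other miRNAs matched on mean signal. It lay past the 95th percentile (0.20) by less than its SE of 0.17, so that the star arms cannot be told apart from such a trend, and an effect of CpG on them stays open. Under the bound first written, without that margin, the star arms and the miR-17 family would both have counted against the trend, and an earlier version of the matching placed both outside the bound too.

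The same trend may underlie, in part or in whole, the lower position of the let-7 and miR-17 families after scaling. Matched lists had a median of -0.22 for let-7 and -0.089 for miR-17. The mean of the let-7 family (-0.37) stood at the 8.39th percentile of matched lists, inside the range that the trend alone gave. That of the miR-17 family (-0.34) stood at the 3.28th percentile, past the 5th (-0.31) by less than its SE of 0.073, so that it cannot be told apart from the trend. Cyclic loess, which removes such a trend, left the families at -0.16 and -0.26 against the other miRNAs and neither passed. The miR-15/16 family stood at the 2.74th percentile of its matched lists (mean -0.34, 5th percentile -0.30, SE 0.12). The miR-23/27/24, miR-29/30 and granulocyte and myeloid lists lay inside the range. The TLR-responsive list stood at the 99.96th (mean 0.41, 95th percentile 0.15), past the bound by more than its SE of 0.17. Members of a family vary together, so that random lists of unrelated miRNAs overstate how far it stands apart, and a response to CpG stays open as untested.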
